A study of Homo sapiens with 19 samples.

How the data were processed

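Total RNA was measured by RNA sequencing in 19 libraries of HepaRG cells, a human hepatic line whose precursors can mature into hepatocyte-like and biliary-like cells. Per the labels' protocols, the cells were differentiated in 12-well plates before siRNA was transfected. Ribosomal RNA was then removed from the extracted RNA, directional libraries were made and paired reads were sequenced on 1 flow cell lane. Libraries fell into 7 groups in 2 batches, as the labels state. Batch 1 held a control siRNA (siNC), an ADAR siRNA and an ADARB1 siRNA, with 3 libraries each. Batch 2 held its own siNC controls (3 libraries), interferon alpha (IFNa, 2 libraries), BX795 (3 libraries) and BX795 with the ADAR siRNA (2 libraries). Per the labels' protocols, siRNA was used at 20 nM, IFNa at 1000 U/mL and BX795 at 1 µM. Both compounds were present from the day of transfection through the media changes at 24 h and 48 h. Whether the wells with IFNa or BX795 alone also received the control siRNA is not given in the sources used here. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between libraries.

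The table held expected counts per gene as deposited by the authors, who used STAR and Salmon with genome build GRCh38.p14 per their processing notes. Tool versions, roles, settings and the annotation release are not given in the sources used here. There was 1 column per library and no scaling between libraries. Of all values, 94.82% lay within 0.005 of a whole number. Counts were rounded to whole numbers, which moved no value by more than 0.5. Gene symbols were found for 61463 of 78894 genes by matching Ensembl identifiers without their version suffix. Positions of the targeted genes were taken from the RefSeq annotation of the same build. Total counts per library ranged from 13.1 to 77.1 M, and the lower totals of batch 2 gave wider errors for weakly expressed genes.

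Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests after trimmed mean of M-values (TMM) scaling and expression filtering with the default settings of filterByExpr. This left 23121 genes, of which 21448 had a symbol. A single model with 1 mean per group was fitted to all 19 libraries, leaving 12 residual degrees of freedom, so that groups of 2 libraries borrowed the spread of the others. The common biological coefficient of variation was 11.2%. Chi-square per gene between replicates was 5.89 to 19.3 in batch 1 and 5.89 to 64.4 in batch 2. A shared spread can thus give p-values that are too small in batch 2 and too large in batch 1. Fits of the compared groups alone called more genes than the shared fit in every batch 1 comparison, and fewer in every batch 2 comparison. Each comparison was made within a batch: ADAR siRNA against siNC, ADARB1 siRNA against siNC and the ADAR against the ADARB1 siRNA in batch 1; IFNa, BX795, and BX795 with ADAR siRNA against siNC, and BX795 with ADAR siRNA against BX795, in batch 2. An interaction contrast compared the ADAR siRNA response with BX795 with the response without it, and crossed the batches. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. All adjusted p-values in the text are from edgeR's quasi-likelihood test with this adjustment unless a list test is named. Levels per group are means of TMM-scaled CPM with the standard deviation (SD), and log2 fold changes carry their standard error (SE). For a group with 0 counts, a floor of 3 counts over the group was set as the limit; such limits cover counting error alone.

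25 lists of genes for the liver, drug metabolism, interferon and other cell programmes were fixed before the data were examined, together with the comparisons, the tests, the alternative settings and the rule for naming genes. The rule named ADAR and ADARB1, the 5 genes with the largest rise and the 5 with the largest fall per comparison, the 3 members with the smallest p of each list with a called member, and 17 pharmacogenes. The 5 genes needed a mean of at least 1 CPM in a compared group, an official symbol and no overlap between the libraries of both groups. Readthrough genes and genes that overlap a near-identical copy were left out. Lists with at least 5 tested members were tested with camera on voom-weighted values (limma 3.58.1), with a preset correlation of 0.01 between genes, and adjusted over the lists within each comparison. The camera test asks whether members moved further than other genes; it was repeated with a correlation estimated per list and beside the fry test, which asks whether members move on balance in 1 direction. A count "adjusted over the list alone" uses the members of the list as the only genes adjusted for. Pharmacogenes as 1 group were the phase I, phase II and transporter lists with NR1I2, NR1I3 and AHR.

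The alternative settings planned beforehand were size factors from DESeq2 1.42.0 in place of TMM, no expression filter, a stricter filter and the DESeq2 test. They also included a fit of 1 batch alone, a fit of the compared groups alone, the replicate number as a block and leaving out each library in turn. The last, a 2-fold cutoff, counted only called genes with an estimated change of at least 2-fold. It was no test against that size. A pair of alternatives was chosen after seeing the data: a correction for GC content, and the batch 2 comparisons without control replicates 2 and 3, which left 1 control library. For the first, the trend of each library on the GC content of transcripts (GENCODE release 29) was removed by a lowess curve with a span of 0.3. GC content was known for 20107 tested genes (87.0%). The GC trend of a library is given as its log2 level of genes over 60% GC minus that of genes under 40% GC. Levels are relative to the mean of the library's own batch.

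The gene test, the list tests and the GC correction were tested on simulated data drawn from the means, totals and spread of the measured libraries, with 200 of 23121 genes changed. In the design of the ADAR siRNA comparison, edgeR recovered 64.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls. For the ADARB1 siRNA the shares were 62.7%, 91.0% and 98.5%, with 14 false calls. For IFNa they were 46.3%, 85.1% and 95.5%, with 3 false calls. For BX795 they were 58.2%, 89.6% and 97.0%, with 7 false calls. For BX795 with ADAR siRNA against siNC they were 53.7%, 76.1% and 97.0%, with 3 false calls. For the interaction they were 43.3%, 71.6% and 92.4%, with 24 false calls. For these gene tests the draws used 1 spread per gene for both batches, independent genes and no GC trend. Their false calls therefore give no rate for the measured batch 2 comparisons, whose libraries differed in GC trend. Of 20 unchanged lists, 1 had an unadjusted p below 0.05 with camera and 1 with fry. Their genes were also drawn independently, so these lists do not test the preset correlation between genes. The GC correction recovered 0.995 of an added trend. No library pair of a group was a duplicate: the lowest chi-square per gene between replicates was 5.89.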

Results

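RNA was measured in differentiated HepaRG cells, a human hepatic line used to study liver drug metabolism, after siRNA against either of a pair of RNA editing enzymes, after interferon alpha and after the kinase inhibitor BX795. ADAR and ADARB1 are adenosine deaminases that act on double-stranded RNA. IFNa is a type I interferon, and BX795 inhibits TBK1 and IKK epsilon, kinases that relay signals from nucleic acid sensors. Batch 1 held 3 siNC control, 3 ADAR siRNA and 3 ADARB1 siRNA libraries, with total counts of 45.8 to 77.1 M, 47.7 to 56.3 M and 42.7 to 64.3 M. Batch 2 held 3 siNC controls with 13.1 to 22.8 M counts and 2 IFNa libraries with 25.0 to 34.7 M. It also held 3 BX795 libraries with 21.5 to 29.2 M and 2 libraries of BX795 with ADAR siRNA with 26.8 to 34.2 M. The questions are which genes follow each knockdown, with attention to pharmacogenes, and how these responses relate to interferon and to BX795. Whether the BX795 responses come from TBK1 or IKK epsilon was not tested. Values after ± are the SE of a log2 fold change or the SD of a level in CPM, and n is the number of libraries. Counts of close relatives or overlapping genes (the CYP2C, CYP3A, UGT1A, UGT2B, GSTA, SAA and metallothionein families) depend on how reads were divided between them, so single members are uncertain to that extent.

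The controls of both batches differed widely, so groups were compared within a batch. Between the batch 2 and batch 1 controls (n = 3 each), 13443 of 23121 tested genes differed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Liver genes were far lower in the batch 2 controls: CYP3A4, a major drug-oxidising enzyme, by a log2 difference of -7.16, CYP2A6 by -9.71 and the plasma protein gene ALB by -2.63. Within batch 2 the controls also stood apart in their base composition. The GC trend (log2 level of genes over 60% GC minus that of genes under 40% GC) was 0.28 in control replicate 1, 1.07 in replicate 2 and 0.87 in replicate 3, against -0.62 to -0.20 with BX795, -0.40 to 0.08 with IFNa, and -0.55 to -0.00 with BX795 and ADAR siRNA. Batch 1 libraries ranged from -0.10 to 0.14. Each batch was centred on its own mean, so only the spread within a batch can be compared between batches. Mitochondrially encoded mRNA made up 1.62% to 3.21% of counts in the batch 2 controls and 4.52% to 4.77% with BX795.

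The targeted genes moved with the labels in every library. ADAR (ENSG00000160710.19; chromosome 1, 154582057 to 154627997 in GRCh38.p14) fell from 262 ± 2.26 CPM in siNC to 64.6 ± 5.32 CPM after ADAR siRNA (n = 3 each), a log2 fold change of -2.02 ± 0.08 with an adjusted p of 1.19e-11. ADARB1 (ENSG00000197381.18; chromosome 21, 45074578 to 45226563) fell from 32.6 ± 1.10 to 10.9 ± 0.559 CPM after ADARB1 siRNA (n = 3 each), a log2 fold change of -1.58 ± 0.07 with an adjusted p of 2.2e-10. ADAR did not change detectably after ADARB1 siRNA (0.03 ± 0.08, adjusted p = 0.936). ADARB1 fell slightly after ADAR siRNA (-0.27 ± 0.07), a call that ended without ADAR siRNA replicate 2 (adjusted p = 0.0507). IFNa raised ADAR to 732 ± 61.6 CPM from 227 ± 26.7 CPM (log2 1.69 ± 0.09, n = 2 against 3), and left ADARB1 at a log2 fold change of -0.00 ± 0.08. In the presence of BX795, ADAR siRNA lowered ADAR from 268 ± 14.5 to 54.1 ± 2.36 CPM (log2 -2.31 ± 0.10, n = 2 against 3).

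**Figure D1:**
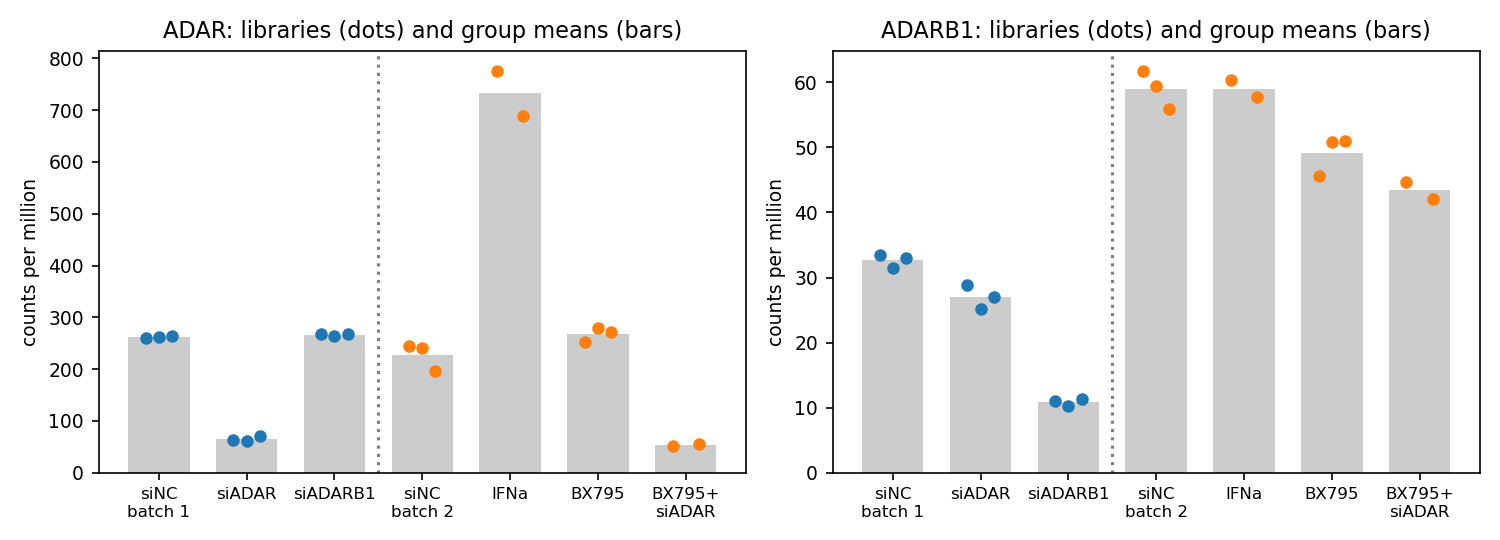
Levels of ADAR and ADARB1 in CPM for each library (dots) with group means (bars), batch 1 left and batch 2 right of the dotted line. ADAR siRNA libraries lie between 60.6 and 70.6 in batch 1 and between 52.5 and 55.8 with BX795, and ADARB1 siRNA libraries between 10.3 and 11.4.

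After ADAR siRNA, interferon stimulated genes rose and many hepatocyte genes fell, while CYP3A4 rose (n = 3 against 3). Of 52 tested type I interferon stimulated genes, 49 rose (50 adjusted over the list alone) and none fell, with a median log2 fold change of 1.31. RSAD2, an antiviral radical SAM enzyme, rose by 6.62 ± 0.53 on the log2 scale, CMPK2 by 4.93 ± 0.53, the antiviral GTPase genes MX2 and MX1 by 4.57 ± 0.20 and 3.61 ± 0.15, IFI44L by 4.33 ± 0.18 and the oligoadenylate synthetase OAS2 by 2.92 ± 0.11. The list's camera test gave an adjusted p of 1.04e-46 (adjusted p = 0.00946 with an estimated correlation). Of 14 interferon genes only IFNE had enough counts to be tested, and it was not called (118 counts over the 3 siNC and 71 over the 3 ADAR siRNA libraries). IFNB1 had 2 counts over the ADAR siRNA libraries, IFNL1 1, IFNL2 5 and IFNL3 6, and each had 0 over the siNC libraries. No fold is given for these 4 genes, since a count of 0 allows up to 3.

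Sensors of double-stranded RNA rose with them: of 17 tested, 8 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.00743 with an estimated correlation). RIGI rose by 2.11 ± 0.14, IFIH1 (MDA5) by 1.03 ± 0.09 and EIF2AK2 (PKR) by 0.90 ± 0.08. Among NF-kB targets and chemokines, 11 of 25 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 9.6e-05, adjusted p = 0.103 with an estimated correlation). CCL2 rose by 2.10 ± 0.12, CXCL10 by 2.08 ± 0.18 and the apoptosis inhibitor BIRC3 by 1.47 ± 0.11. MHC class I antigen presentation followed with 9 of 18 genes up (11 adjusted over the list alone, adjusted p = 9.09e-06, adjusted p = 0.0851 with an estimated correlation). The peptide transporter TAP1 rose by 0.60 ± 0.10 and the immunoproteasome subunit PSMB9 by 0.59 ± 0.10. The DNA deaminase APOBEC3G also rose by 0.79 ± 0.09. IGFL1, a secreted growth factor-like protein, rose by 4.24 ± 0.25, while the epidermal protease gene CASP14 fell by 3.90 ± 0.39, the methyltransferase INMT by 2.67 ± 0.26 and the synaptic adhesion gene LRRTM3 by 2.66 ± 0.34.

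**Figure D2:**
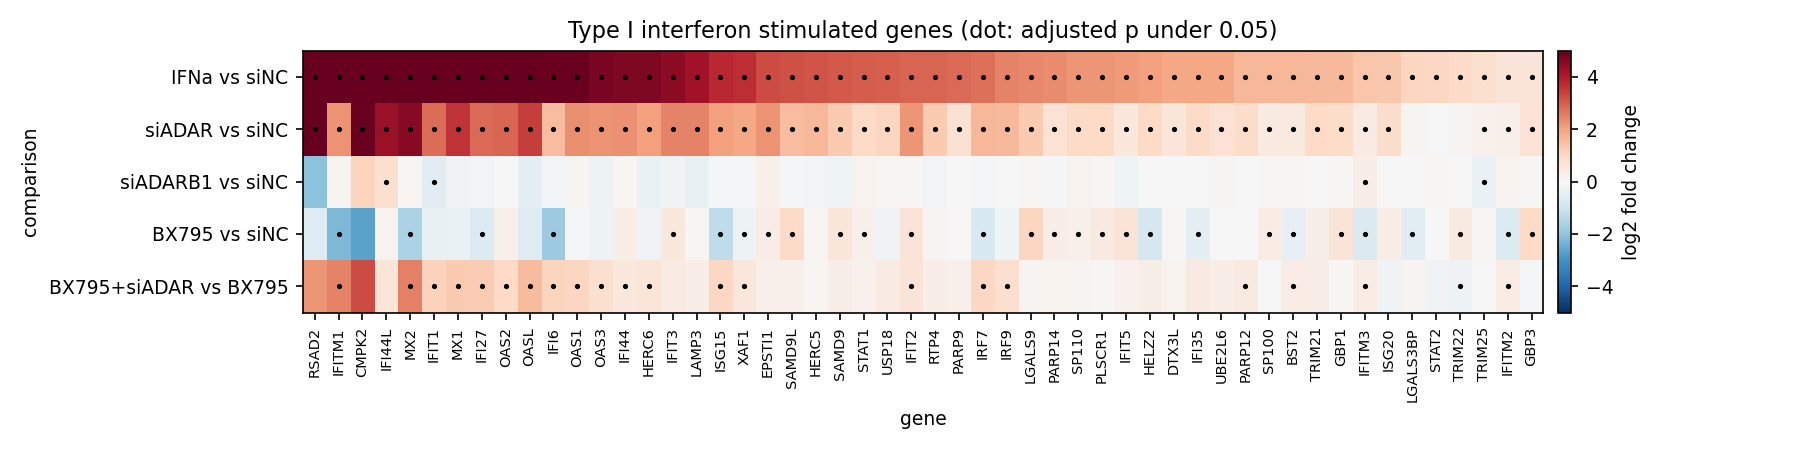
Log2 fold change (colour) of the 52 type I interferon stimulated genes in 5 comparisons, with a dot where the adjusted p was under 0.05, ordered by the response to IFNa. The list's median was 2.92 with IFNa, 1.31 after ADAR siRNA, -0.01 after ADARB1 siRNA, 0.01 with BX795 and 0.36 for ADAR siRNA in the presence of BX795.

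More pharmacogenes fell than rose after ADAR siRNA, and CYP3A4 (ENSG00000160868.16) was among those that rose. CYP3A4 went from 225 ± 13.3 to 1059 ± 50.3 CPM, a log2 fold change of 2.24 ± 0.11. Of 101 tested pharmacogenes, 43 fell and 11 rose (54 and 18 adjusted over the list alone; camera adjusted p = 5.34e-08, adjusted p = 0.0368 with an estimated correlation). In the phase I list 19 of 40 fell and 7 rose (24 and 8 adjusted over the list alone, adjusted p = 5.71e-05, adjusted p = 0.125 with an estimated correlation). The alcohol dehydrogenase ADH4 at -1.19 ± 0.09, CYP2C8 at -0.83 ± 0.09, CYP1B1 at -0.80 ± 0.07 and CYP3A5 at -0.39 ± 0.08 fell, and the ethanol-oxidising CYP2E1 rose by 0.33 ± 0.08. In phase II 12 of 36 fell and 2 rose (15 and 6 adjusted over the list alone, adjusted p = 9.57e-05, adjusted p = 0.0171 with an estimated correlation). The glycine conjugating GLYAT fell by 1.12 ± 0.11, the glutathione transferase GSTA1 by 0.98 ± 0.06 and UGT1A9 by 0.54 ± 0.06. Of 22 drug transporters 11 fell and 2 rose (11 and 4 adjusted over the list alone, adjusted p = 0.000972, adjusted p = 0.038 with an estimated correlation). The phospholipid exporter ABCB4 fell by 0.80 ± 0.08 and the drug efflux pump ABCB1 by 0.56 ± 0.08. CYP2B6 (-0.22 ± 0.09), CYP2C19 (-0.35 ± 0.13), CYP1A2 (0.55 ± 0.19), UGT1A1 (0.15 ± 0.08) and the drug-sensing receptor NR1I2 (-0.32 ± 0.12) did not pass, with adjusted p of 0.0508 or more, although all 5 passed in a fit of batch 1 alone.

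**Figure D3:**
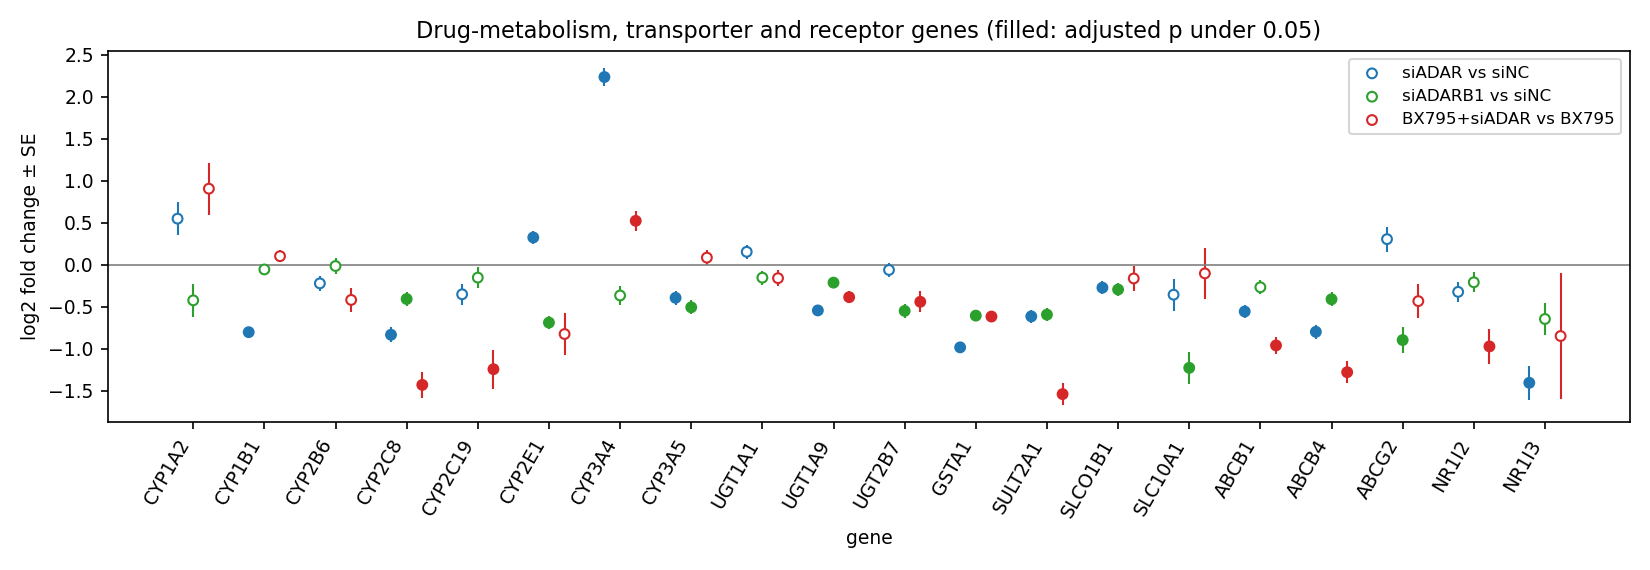
Log2 fold change with its SE for 20 pharmacogenes after ADAR siRNA, after ADARB1 siRNA (both batch 1, n = 3 against 3) and for ADAR siRNA in the presence of BX795 (batch 2, n = 2 against 3); filled points had an adjusted p under 0.05. CYP3A4 stands at 2.24, -0.36 and 0.52 in these comparisons.

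Liver transcription factors and other hepatocyte genes moved down with the pharmacogenes. HepaRG cells can mature into hepatocyte-like and biliary-like cells, and the libraries were not separated by cell type. Changes within cells therefore cannot be told apart from changes in the share of each cell type, here and in the other comparisons. Of 26 receptors and transcription factors 13 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 9.09e-06, adjusted p = 0.0232 with an estimated correlation). NR1I3 (CAR) fell by 1.41 ± 0.20, ONECUT1 by 0.80 ± 0.09 and HNF4A by 0.68 ± 0.08, while the vitamin D receptor VDR rose by 0.80 ± 0.09. Among 30 secreted and metabolic hepatocyte markers 19 fell and 2 rose (22 and 2 adjusted over the list alone, adjusted p = 6.89e-10, adjusted p = 0.0733 with an estimated correlation). The tryptophan oxygenase TDO2 fell by 1.64 ± 0.11, and the urea cycle genes CPS1 and OTC by 1.25 ± 0.11 and 0.70 ± 0.07. Of 20 genes for bile acid synthesis and transport 12 fell (12 adjusted over the list alone), led by CYP7A1, the rate-limiting enzyme of the main pathway, at -1.36 ± 0.10 (adjusted p = 1.86e-07, adjusted p = 0.0263 with an estimated correlation). In the other direction, 8 of 12 biliary and progenitor markers rose and 1 fell (8 and 2 adjusted over the list alone, adjusted p = 0.000376, adjusted p = 0.0126 with an estimated correlation). SPP1 rose by 1.43 ± 0.08, the keratin KRT19 by 1.22 ± 0.12 and ITGB4 by 0.82 ± 0.12. Of 20 mesenchymal and matrix genes 9 rose and 1 fell, the same numbers when adjusted over the list alone (adjusted p = 0.00049, adjusted p = 0.037 with an estimated correlation). POSTN rose by 1.34 ± 0.10, and the collagen COL3A1 fell by 1.47 ± 0.16. Cell cycle genes rose in 15 of 25 cases (17 adjusted over the list alone, adjusted p = 6.89e-10, adjusted p = 0.037 with an estimated correlation). The replication helicase MCM6 rose by 0.51 ± 0.06 and TYMS by 0.51 ± 0.08. Of 20 p53 targets 7 rose and 1 fell, again the same when adjusted over the list alone (adjusted p = 0.000138, adjusted p = 0.00946 with an estimated correlation), CDKN1A by 0.57 ± 0.06 among them. Endoplasmic reticulum chaperones of the unfolded protein response rose in 6 of 16 cases (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.00371, adjusted p = 0.0368 with an estimated correlation), PDIA4 by 0.76 ± 0.07.

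In total, 5042 genes changed after ADAR siRNA, 2539 up and 2503 down, of which 780 had an estimated change of at least 2-fold. A fit of batch 1 alone called 8156 genes and one of both compared groups alone 8028. Camera with both GC correction and an estimated correlation no longer called several lists. Pharmacogenes, phase II, bile acid, cell cycle and chaperone lists stood at an adjusted p of 0.0635 and transporters at 0.0679. MHC class I was called there (adjusted p = 0.0334).

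ADARB1 siRNA gave a smaller response without an interferon signature (n = 3 against 3). MT1F and MT1E, which encode metal-binding proteins, rose by 2.63 ± 0.27 and 1.70 ± 0.08 (the latter from 33.2 ± 2.72 to 108 ± 2.39 CPM), beside the tachykinin gene TAC1 at 2.23 ± 0.33 and the synaptic gene SYN1 at 1.81 ± 0.28. IGFBP5, an insulin-like growth factor binding protein, fell by 1.54 ± 0.11 and the T cell costimulator gene TNFRSF9 by 1.38 ± 0.20. Of the 52 interferon stimulated genes 2 rose and 2 fell (2 and 2 adjusted over the list alone). The list did not move as a whole (camera adjusted p = 0.936, toward higher values; median -0.01). As after ADAR siRNA, unfolded protein response chaperones rose in 6 of 16 cases (9 adjusted over the list alone, camera adjusted p = 1.47e-09, adjusted p = 0.00131 with an estimated correlation). PDIA4 rose by 1.03 ± 0.07, HSP90B1 by 0.44 ± 0.06 and HSPA5 by 0.36 ± 0.05. The acute-phase protein gene CRP rose by 1.16 ± 0.08. It was 1 of 3 risers among 20 acute-phase genes (3 adjusted over the list alone, adjusted p = 0.0143, adjusted p = 0.422 with an estimated correlation).

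Drug metabolism and bile acid genes fell after ADARB1 siRNA, compared with the same 3 siNC libraries as for ADAR siRNA. Tested directly between the knockdowns, camera called neither the pharmacogenes (adjusted p = 0.797) nor the bile acid genes (adjusted p = 0.351). The falls are thus not shown to be particular to ADARB1 siRNA, and part of them can come from the shared controls. Of 101 pharmacogenes 29 fell and 5 rose (41 and 5 adjusted over the list alone; camera adjusted p = 1.2e-19, adjusted p = 0.00292 with an estimated correlation). The phase I list had 13 falls and 2 rises among 40 (18 and 2 adjusted over the list alone, adjusted p = 1.11e-13, adjusted p = 0.0235 with an estimated correlation). ADH1A fell by 0.91 ± 0.12, CYP2E1 by 0.69 ± 0.08 and CYP3A5 by 0.51 ± 0.08, while the monoamine oxidase MAOB rose by 0.88 ± 0.07. CYP3A4 stood at -0.36 ± 0.11 and did not pass (adjusted p = 0.0644), although several alternatives called it lower. Phase II had 10 falls and 3 rises among 36 (12 and 3 adjusted over the list alone, adjusted p = 7.73e-08, adjusted p = 0.00292 with an estimated correlation). GSTA1 and the sulfotransferase SULT2A1 fell by 0.60 ± 0.06 and 0.59 ± 0.07, and SULT1C2 rose by 0.79 ± 0.08. Transporters fell in 6 of 22 cases (11 adjusted over the list alone, adjusted p = 6.63e-09, adjusted p = 0.00292 with an estimated correlation). The bile acid importer SLC10A1 fell by 1.23 ± 0.19 and the efflux pump ABCG2 by 0.90 ± 0.15. Of 20 bile acid genes 7 fell (11 adjusted over the list alone, adjusted p = 4.84e-12, adjusted p = 0.00585 with an estimated correlation). CYP7A1 fell by 0.87 ± 0.10 and AKR1C4 by 0.81 ± 0.11. Hepatocyte markers fell in 9 of 30 cases (17 lower and 2 higher adjusted over the list alone, adjusted p = 1.44e-10, adjusted p = 0.116 with an estimated correlation). OTC fell by 0.57 ± 0.07 and the fatty acid binding protein FABP1 by 0.59 ± 0.09. Cell cycle genes fell in 5 of 25 cases (8 adjusted over the list alone), RRM2 by 0.79 ± 0.13 and PLK1 by 0.86 ± 0.16 (adjusted p = 1.2e-06, adjusted p = 0.139 with an estimated correlation). Mesenchymal and matrix genes rose in 4 of 20 cases and fell in 1 (4 and 2 adjusted over the list alone, adjusted p = 0.0304, adjusted p = 0.206 with an estimated correlation), POSTN falling by 0.84 ± 0.10. Of 12 biliary and progenitor markers 2 rose (2 adjusted over the list alone), SPP1 by 0.90 ± 0.08. Camera did not call this list (adjusted p = 0.187, toward higher values, median -0.01), but fry called it higher (adjusted p = 0.000297).

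After ADARB1 siRNA 1066 genes changed, 485 up and 581 down, and 88 by at least 2-fold. The count was unstable: it was 603 to 702 with any 1 of the 6 libraries left out (603 without ADARB1 siRNA replicate 1), 1663 with DESeq2, 1838 after GC correction and 3557 in a fit of batch 1 alone.

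Tested directly against each other (n = 3 each), the knockdowns differed in 4518 genes, 2288 higher and 2230 lower after ADAR siRNA, and in 686 by at least 2-fold. A fit of batch 1 alone gave 7676. Interferon stimulated genes were higher after ADAR siRNA in 47 of 52 cases (48 adjusted over the list alone; camera adjusted p = 6.08e-48, adjusted p = 0.0128 with an estimated correlation). OASL was higher by 3.90 ± 0.19 and XAF1 by 2.02 ± 0.09. Cell cycle genes were higher in 23 of 25 cases (24 adjusted over the list alone, adjusted p = 4.31e-19, adjusted p = 0.0139 with an estimated correlation). RRM2 stood at 1.02 ± 0.13 and TOP2A at 0.78 ± 0.09. Camera did not call unfolded protein response chaperones, with 2 of 16 lower after ADAR siRNA (1 adjusted over the list alone, adjusted p = 0.0605). The fry test called the list lower (adjusted p = 0.000258). Camera after GC correction did so too (adjusted p = 0.0407, 0.279 with an estimated correlation). CYP3A4 was higher by 2.60 ± 0.11, CYP2E1 by 1.01 ± 0.08, CYP1A2 by 0.97 ± 0.20 and ABCG2 by 1.20 ± 0.15. In contrast, CRP (-1.42 ± 0.08), SULT1C2 (-1.27 ± 0.08), TDO2 (-1.21 ± 0.11) and HNF4A (-0.68 ± 0.08) were lower. The pharmacogene list as a whole showed no difference in direction, with 26 higher and 29 lower of 101 (27 and 32 adjusted over the list alone, adjusted p = 0.797, median -0.02 and mean 0.04). Of the genes called in both knockdowns, 305 rose in both and 250 fell in both, where independent lists would share 53.3 and 62.9; 75 rose after ADAR siRNA and fell after ADARB1 siRNA and 32 did the reverse, against 63.8 and 52.5. Fold changes correlated across genes (r = 0.427, covariance 0.178; genes are not independent replicates). Simulated unchanged groups sharing the same controls gave a mean r of 0.488 (0.443 to 0.518), a covariance of 0.0979 (0.0854 to 0.107) and 0 shared calls over 20 draws. The 3 controls were too few to split, so part of the excess in shared calls can come from them.

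Interferon alpha raised every tested gene of the interferon list (n = 2 against 3). All 52 rose (52 adjusted over the list alone), with a median log2 fold change of 2.92 (camera adjusted p = 2.07e-75, adjusted p = 0.00379 with an estimated correlation). IFITM1, which restricts viral entry, rose by 7.80 ± 0.27, CMPK2 by 6.44 ± 0.50, IFI44L by 6.17 ± 0.19, IFI27 by 5.36 ± 0.16 and OAS2 by 5.32 ± 0.13. The sensors RIGI and IFIH1 rose by 4.41 ± 0.17 and 2.86 ± 0.11 and EIF2AK2 by 1.84 ± 0.09. Their sensing list had 9 of 17 genes up and 3 down (10 and 4 adjusted over the list alone, adjusted p = 0.00237, adjusted p = 0.0337 with an estimated correlation). MHC class I genes rose in 15 of 18 cases and fell in 1 (15 and 1 adjusted over the list alone, adjusted p = 4.37e-11, adjusted p = 0.0622 with an estimated correlation). The light chain B2M rose by 1.37 ± 0.09, TAP2 by 0.89 ± 0.07 and HLA-E by 0.79 ± 0.08. After GC correction all 52 interferon stimulated genes and 13 of these 15 MHC class I genes were still called higher.

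Pharmacogenes went both ways with IFNa: 18 of 101 rose and 20 fell (19 and 20 adjusted over the list alone; camera adjusted p = 0.972, median -0.05), and 11 and 16 of these calls held after GC correction. CYP2B6 fell by 2.02 ± 0.30, CYP2E1 by 1.07 ± 0.18, UGT1A1 by 0.55 ± 0.10 and the organic anion transporter SLC22A7 by 1.47 ± 0.24. The epoxygenase CYP2J2 rose by 1.07 ± 0.13, CYP2C8 by 0.68 ± 0.13 and CYP3A5 by 0.59 ± 0.09. In a fit of both compared groups alone CYP2E1, UGT1A1 and CYP2C8 did not pass (adjusted p = 0.059, 0.06 and 0.063). GC correction moved CYP2C8 to 0.43 and CYP3A5 to 0.34, and without control replicates 2 and 3 SLC22A7 stood at -0.84 and UGT1A1 at -0.32. CYP3A4 stood at 0.73 ± 0.25 (adjusted p = 0.0287), but the call ended without any 1 of control replicates 1, 2 and 3 (0.78, 0.80 and 0.66), without IFNa replicate 1 (0.46, adjusted p = 0.372) and after GC correction (0.47, adjusted p = 0.149). Acute-phase genes fell in 10 of 20 cases (10 adjusted over the list alone, adjusted p = 0.000827, adjusted p = 0.767 with an estimated correlation). The fibrinogen chain FGA fell by 0.54 ± 0.10 and the haem-binding HPX by 0.96 ± 0.16, and 7 of the 10 falls held after GC correction. Hepatocyte markers fell in 16 of 30 cases and rose in 2 (17 and 2 adjusted over the list alone, adjusted p = 0.00237, adjusted p = 0.767 with an estimated correlation). Of these falls 12 held.

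IFNa changed 7932 genes, 4250 up and 3682 down, and 1119 by at least 2-fold. The majority direction depended on the scaling: DESeq2 size factors gave 3913 up and 4035 down, and GC correction 2954 up and 3113 down. Fold changes ran against GC content across genes (Spearman's rho -0.487; genes are not independent replicates), and after GC correction 6067 genes were called, 4454 of them called in the same direction before it. The count was 1966 without control replicates 2 and 3, 2652 without IFNa replicate 1 and 1695 in a fit of both compared groups alone.

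The ADAR knockdown and IFNa responses were more alike for interferon stimulated genes than for all tested genes or pharmacogenes (r = -0.005 across pharmacogenes). No other list was compared in this way. Across all tested genes the fold changes correlated at r = 0.063 (0.159 among genes of at least 1 CPM), at r = 0.89 across the 52 list members and at r = 0.039 without them; genes are not independent replicates. Of 117 genes that IFNa raised at least 4-fold, ADAR siRNA raised 56 and lowered 2, with a median log2 fold change of 0.89. Among all genes 723 rose in both and 552 fell in both, where independent lists would share 466.7 and 398.6. Calls in opposite directions also exceeded those of independent lists: 425 genes rose after ADAR siRNA and fell with IFNa (404.3), and 553 did the reverse (460.1). Without the interferon list 674 rose in both and 552 fell in both, against 453.1 and 399.5 for independent lists. These comparisons share no library and come from different batches, whose controls differed widely.

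With BX795 alone, CYP3A4 had the largest rise by fold among the genes named here (n = 3 against 3). CYP3A4 went from 1.54 ± 0.250 to 71.9 ± 8.32 CPM, a log2 fold change of 5.52 ± 0.17. CYP2B6 rose by 1.95 ± 0.17, the pattern receptor gene CLEC4E by 3.90 ± 0.32, the interleukin 33 receptor IL1RL1 by 3.51 ± 0.15 and the mucin MUC13 by 3.02 ± 0.20. The transcription factor CREB3L1 fell by 4.26 ± 0.28 and the imprinted RNA H19 by 3.90 ± 0.24. NF-kB targets and chemokines rose in 17 of 25 cases and fell in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 1.28e-07, adjusted p = 0.112 with an estimated correlation). CXCL8 rose by 1.57 ± 0.09, CXCL1 by 1.39 ± 0.10 and the feedback inhibitor TNFAIP3 by 1.25 ± 0.08. All 17 rises held after GC correction, which moved CXCL8 to 0.97.

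Several secretory, stress and growth groups fell with BX795. Acute-phase genes fell in 14 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 4.42e-06, adjusted p = 0.367 with an estimated correlation). HPX fell by 1.68 ± 0.15, FGA by 1.06 ± 0.09 and haptoglobin HP by 0.98 ± 0.09, and 11 of the list's falls held after GC correction. Unfolded protein response chaperones fell in 9 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.000247, adjusted p = 0.0446 with an estimated correlation). CALR fell by 1.27 ± 0.08, HYOU1 by 1.02 ± 0.07 and HSPA5 by 0.86 ± 0.05, and all 9 falls held. Cell cycle genes fell in 18 of 25 cases (20 adjusted over the list alone, adjusted p = 2.73e-06, adjusted p = 0.293 with an estimated correlation). BIRC5 fell by 1.59 ± 0.15, MKI67 by 0.92 ± 0.11 and MCM4 by 0.70 ± 0.07, and 15 of the falls held. Mesenchymal and matrix genes fell in 10 of 20 cases and rose in 4 (11 and 4 adjusted over the list alone), with POSTN at -1.54 ± 0.11 and COL5A1 at -1.59 ± 0.14 (adjusted p = 0.0464, adjusted p = 0.357 with an estimated correlation). Of these falls 7 held after GC correction, but the list's own call ended (adjusted p = 0.0589). Targets of insulin and FOXO signalling rose in 8 of 15 cases and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.00308, adjusted p = 0.0586 with an estimated correlation). PDK4 rose by 1.74 ± 0.11 and TXNIP by 1.16 ± 0.09, and 6 of the rises held. Mitochondrially encoded mRNAs rose in 9 of 13 cases and fell in 1, the same when adjusted over the list alone, MT-CO1 by 1.15 ± 0.18 (0.67 without control replicates 2 and 3). The camera test gave an adjusted p of 0.00228 (adjusted p = 0.597 with an estimated correlation).

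Pharmacogenes went both ways with BX795, 26 up and 38 down of 101 (28 and 40 adjusted over the list alone, camera adjusted p = 0.399, median -0.16). After GC correction 15 and 33 of these calls held, and camera called the group lower (adjusted p = 0.0331, 0.522 with an estimated correlation). The aldehyde dehydrogenase ALDH2 rose by 1.07 ± 0.07, MGST1 by 1.37 ± 0.11, UGT1A6 by 0.85 ± 0.07, UGT1A1 by 0.82 ± 0.09 and ABCB1 by 0.54 ± 0.09 (0.26 after GC correction). CYP1B1 fell by 1.39 ± 0.07, SULT2A1 by 1.47 ± 0.10, CYP2E1 by 1.40 ± 0.18, SLC22A7 by 3.14 ± 0.26 and NR1I2, the receptor PXR, by 1.09 ± 0.16. Interferon stimulated genes split, with 15 up and 13 down of 52 (15 and 13 adjusted over the list alone). Camera did not call the list (adjusted p = 0.834, toward higher values, median 0.01 and mean -0.14). After GC correction only 5 of the rises and 8 of the falls held. RIGI rose by 1.53 ± 0.17 and STING1, the adaptor of DNA sensing, fell by 1.43 ± 0.08. ADAR itself was called higher by 0.24 ± 0.08, a call that ended without control replicate 3 (0.16), without BX795 replicate 2 (0.21), without BX795 replicate 3 (0.23) and in a fit of both groups alone (adjusted p = 0.104).

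With BX795 10885 genes changed, 5408 up and 5477 down, and 2331 by at least 2-fold. Fold changes ran against GC content across genes (rho -0.563; genes are not independent replicates). After GC correction 8199 genes were called, 5908 in the same direction as before and 434 in the opposite one, and without control replicates 2 and 3 the count was 4688. That fit had 1 control library left, so its count mixes lost replication with the removal of GC-rich libraries.

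BX795 together with ADAR siRNA, compared with siNC (n = 2 against 3), gave CYP3A4 at 6.04 ± 0.18 on the log2 scale (103 ± 26.8 CPM) and CYP2B6 at 1.54 ± 0.19. Interferon stimulated genes rose in 31 of 52 cases and fell in 6 (32 and 6 adjusted over the list alone), OAS2 by 1.24 ± 0.13, with a list median of 0.47 (camera adjusted p = 2.43e-05, adjusted p = 0.345 with an estimated correlation); 21 of the rises held after GC correction. NF-kB targets rose in 15 of 25 cases (15 adjusted over the list alone, adjusted p = 3.21e-09, adjusted p = 0.0517 with an estimated correlation). CXCL8 rose by 1.92 ± 0.10, CXCL1 by 1.72 ± 0.11 and TNFAIP3 by 1.42 ± 0.09, and all 15 rises held. Acute-phase genes fell in 15 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone, adjusted p = 2.74e-11, adjusted p = 0.0717 with an estimated correlation). CRP fell by 2.31 ± 0.14, HP by 2.16 ± 0.10 and FGA by 1.98 ± 0.11, and all 15 falls held. Cell cycle genes fell in 22 of 25 cases (22 adjusted over the list alone, adjusted p = 5.43e-14, adjusted p = 0.0517 with an estimated correlation). BIRC5 fell by 3.59 ± 0.21, MKI67 by 2.29 ± 0.13 and TOP2A by 2.27 ± 0.12, and 21 of the falls held. Cholesterol synthesis genes rose in 15 of 23 cases and fell in 2 (15 and 2 adjusted over the list alone), IDI1 by 1.05 ± 0.12. Camera gave an adjusted p of 9.04e-05 for this list (adjusted p = 0.0912 with an estimated correlation).

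Pharmacogenes fell in 42 of 101 cases and rose in 17 (44 and 17 adjusted over the list alone; camera adjusted p = 0.000816, adjusted p = 0.176 with an estimated correlation), and 39 and 16 of these calls held after GC correction. SULT2A1 fell by 3.00 ± 0.12, ADH4 by 2.71 ± 0.23, CYP2E1 by 2.22 ± 0.22, NR1I2 by 2.06 ± 0.20, UGT2B4 by 1.99 ± 0.14 and CYP2C8 by 1.59 ± 0.15. Of the hepatocyte markers 20 of 30 fell and 2 rose (21 and 2 adjusted over the list alone, adjusted p = 3.55e-06, adjusted p = 0.215 with an estimated correlation). FABP1 fell by 3.12 ± 0.29, TDO2 by 2.51 ± 0.14 and the receptor gene ASGR1 by 2.45 ± 0.17, and 15 of the falls held. In all, 9310 genes changed, 4942 up and 4368 down, and 2088 by at least 2-fold, with fold changes running against GC content (rho -0.466 across genes, which are not independent replicates). After GC correction 7813 genes were called (3623 up and 4190 down), 5770 in the same direction as before. DESeq2 size factors gave 4454 up and 4843 down, so the majority direction depended on the scaling. The count was 4671 without control replicates 2 and 3 (1 control library left), 5275 without replicate 2 of BX795 with ADAR siRNA, and 4188 in a fit of both compared groups alone.

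Against BX795 alone (n = 2 against 3), ADAR siRNA still raised interferon stimulated genes, 21 of 52, and lowered 1 (29 and 2 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 2.62e-11, adjusted p = 0.148 with an estimated correlation); MX2 rose by 2.53 ± 0.26, OAS2 by 0.99 ± 0.12 and the signalling factor IRF9 by 0.84 ± 0.10. The alkaline phosphatase ALPP rose by 2.33 ± 0.12, FGFBP1 by 2.28 ± 0.38 and H19 by 1.93 ± 0.28, and CASP14 and the retinol dehydrogenase RDH16 fell by 2.60 ± 0.34 and 2.79 ± 0.38. Cell cycle genes fell in 15 of 25 cases (21 adjusted over the list alone, adjusted p = 1.73e-14, adjusted p = 0.0274 with an estimated correlation). BIRC5 fell by 2.00 ± 0.22, TOP2A by 1.60 ± 0.12 and MKI67 by 1.37 ± 0.13. Cholesterol synthesis genes rose in 11 of 23 cases (16 adjusted over the list alone, adjusted p = 2.72e-09, adjusted p = 0.0274 with an estimated correlation). SQLE rose by 0.53 ± 0.08 and FDPS by 0.40 ± 0.06. Chaperones of the unfolded protein response rose in 6 of 16 cases (7 adjusted over the list alone), PDIA4 by 0.66 ± 0.08 (adjusted p = 0.000455, adjusted p = 0.0274 with an estimated correlation). Acute-phase genes fell in 12 of 20 cases and rose in 1 (14 and 2 adjusted over the list alone), HP by 1.18 ± 0.10 (adjusted p = 3.1e-11, adjusted p = 0.0657 with an estimated correlation).

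Pharmacogenes fell in 29 of 101 cases and rose in 7 (37 and 11 adjusted over the list alone; camera adjusted p = 2.11e-07, adjusted p = 0.052 with an estimated correlation). Phase II genes fell in 10 of 36 cases (11 lower and 1 higher adjusted over the list alone, adjusted p = 3.17e-05, adjusted p = 0.0231 with an estimated correlation), SULT2A1 by 1.54 ± 0.13 and GSTA1 by 0.62 ± 0.07. Transporters fell in 7 of 22 cases and rose in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.000174, adjusted p = 0.0274 with an estimated correlation), ABCB4 by 1.28 ± 0.13 and ABCB1 by 0.96 ± 0.10. CYP2C8 fell by 1.43 ± 0.15 and HNF4A by 0.60 ± 0.10, and the aldehyde dehydrogenase ALDH3A1 rose by 1.15 ± 0.12. CYP3A4 was called higher by 0.52 ± 0.12 (adjusted p = 0.00913), a call that ended without replicate 2 of BX795 with ADAR siRNA (0.23, adjusted p = 0.257) and in a fit of batch 2 alone (adjusted p = 0.136).

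This comparison called 2201 genes, 1170 up and 1031 down, and 384 by at least 2-fold. DESeq2 size factors gave 887 up and 1226 down, so the share of rises went from 53.2% to 42.0%. After GC correction none of its lists was called with an estimated correlation, and all 5 called before (cell cycle, cholesterol synthesis, chaperones, phase II and transporters) stood at an adjusted p of 0.0909. The count was 712 in a fit of batch 2 alone (275 up and 437 down), 962 in a fit of both groups alone, 1209 without replicate 1 of BX795 with ADAR siRNA and 3353 after GC correction.

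The response to ADAR siRNA with BX795 minus the response without it was tested gene by gene, with the former from batch 2 and the latter from batch 1, so BX795 and batch cannot be separated in this contrast. The difference is signed: a higher response can be a smaller fall, and a lower one a smaller rise or a fall. Interferon stimulated genes responded less in the presence of BX795: 32 of 52 had a lower response and none a higher one (42 adjusted over the list alone), with a median difference of -0.89 (camera adjusted p = 5.81e-49, adjusted p = 0.00589 with an estimated correlation). The difference was -3.71 ± 0.28 for IFI44L, -2.02 ± 0.19 for EPSTI1, -1.93 ± 0.17 for OAS2 and -1.66 ± 0.21 for RIGI, and among chemokines -4.25 ± 0.53 for CCL5, -2.14 ± 0.27 for CXCL10 and -1.28 ± 0.17 for CCL2. Cell cycle genes, 15 of 25 of which rose without BX795 and 15 of which fell with it, had a lower response in 20 cases (23 adjusted over the list alone), by -2.60 ± 0.25 for BIRC5, -2.00 ± 0.15 for TOP2A and -1.82 ± 0.16 for MKI67 (adjusted p = 2.3e-37, adjusted p = 0.00241 with an estimated correlation). p53 targets had a lower response as a list, with 1 of 20 called lower (4 adjusted over the list alone, adjusted p = 5.27e-06, adjusted p = 0.00241 with an estimated correlation), BTG2 at -0.65 ± 0.10. The difference was positive for fatty acid synthesis genes, 3 of 15 called (7 adjusted over the list alone, adjusted p = 5.26e-07, adjusted p = 0.0181 with an estimated correlation and 0.0913 after GC correction as well), with GPAM at 0.96 ± 0.13, PNPLA3 at 0.75 ± 0.13 and ACSS2 at 0.71 ± 0.08. This does not mean a larger response. Without BX795 the list's median was -0.20, with 2 higher and 6 lower of 15 (camera adjusted p = 0.00933, 0.128 with an estimated correlation). With BX795 it was 0.19 (4 higher and 1 lower, list not called, camera adjusted p = 0.0585), so a change of direction is not shown for the list. For cholesterol synthesis genes the difference was positive in 2 of 23 cases (12 adjusted over the list alone). Camera gave an adjusted p of 2.29e-10 (0.0131 with an estimated correlation and 0.0584 after GC correction as well). MVK, at 0.66 ± 0.12, went from a fall to a rise.

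Among pharmacogenes the responses differed in 15 of 101 cases, 7 higher and 8 lower (8 and 16 adjusted over the list alone; camera adjusted p = 0.128, median -0.03). CYP3A4 had a lower response by -1.71 ± 0.17 and SULT2A1 by -0.93 ± 0.15, and CYP1B1 had a higher one by 0.91 ± 0.10. ADAR's own fall did not differ detectably (-0.29 ± 0.12, adjusted p = 0.266). In total 790 genes differed, 328 with a higher and 462 with a lower response, and 271 by at least 2-fold. The count was 442 without replicate 1 of BX795 with ADAR siRNA, 515 without ADAR siRNA replicate 2, 1211 with DESeq2 and 1407 after GC correction.

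Gene by gene, the 2 ADAR siRNA responses shared 778 rises and 636 falls, where independent lists would share 128.5 and 111.6. Opposite calls numbered 89 (higher without BX795) and 18, against 113.2 and 126.7. The fold changes correlated across genes at r = 0.123 (0.32 among genes of at least 1 CPM), across interferon stimulated genes at r = 0.799 and across pharmacogenes at r = 0.547; genes are not independent replicates.

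**Figure D4:**
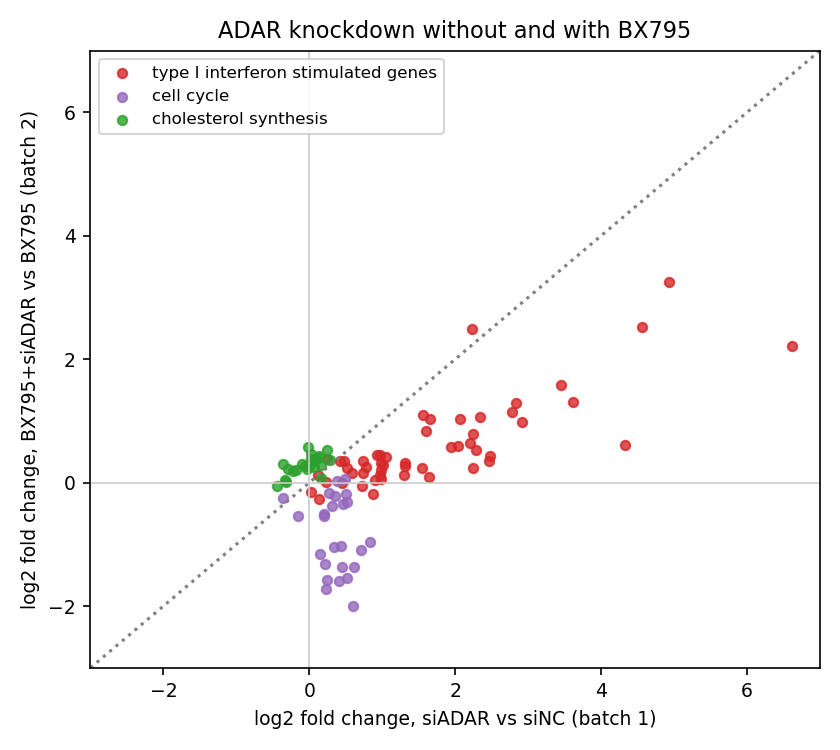
Log2 fold change after ADAR siRNA in batch 1 (x axis) and in the presence of BX795 in batch 2 (y axis) for interferon stimulated, cell cycle and cholesterol synthesis genes, with equality as a dotted line. Interferon stimulated genes lie mostly below the line (median difference -0.89), and cell cycle genes rise on the x axis (median 0.38) and fall on the y axis (median -0.96).

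**Figure D5:**
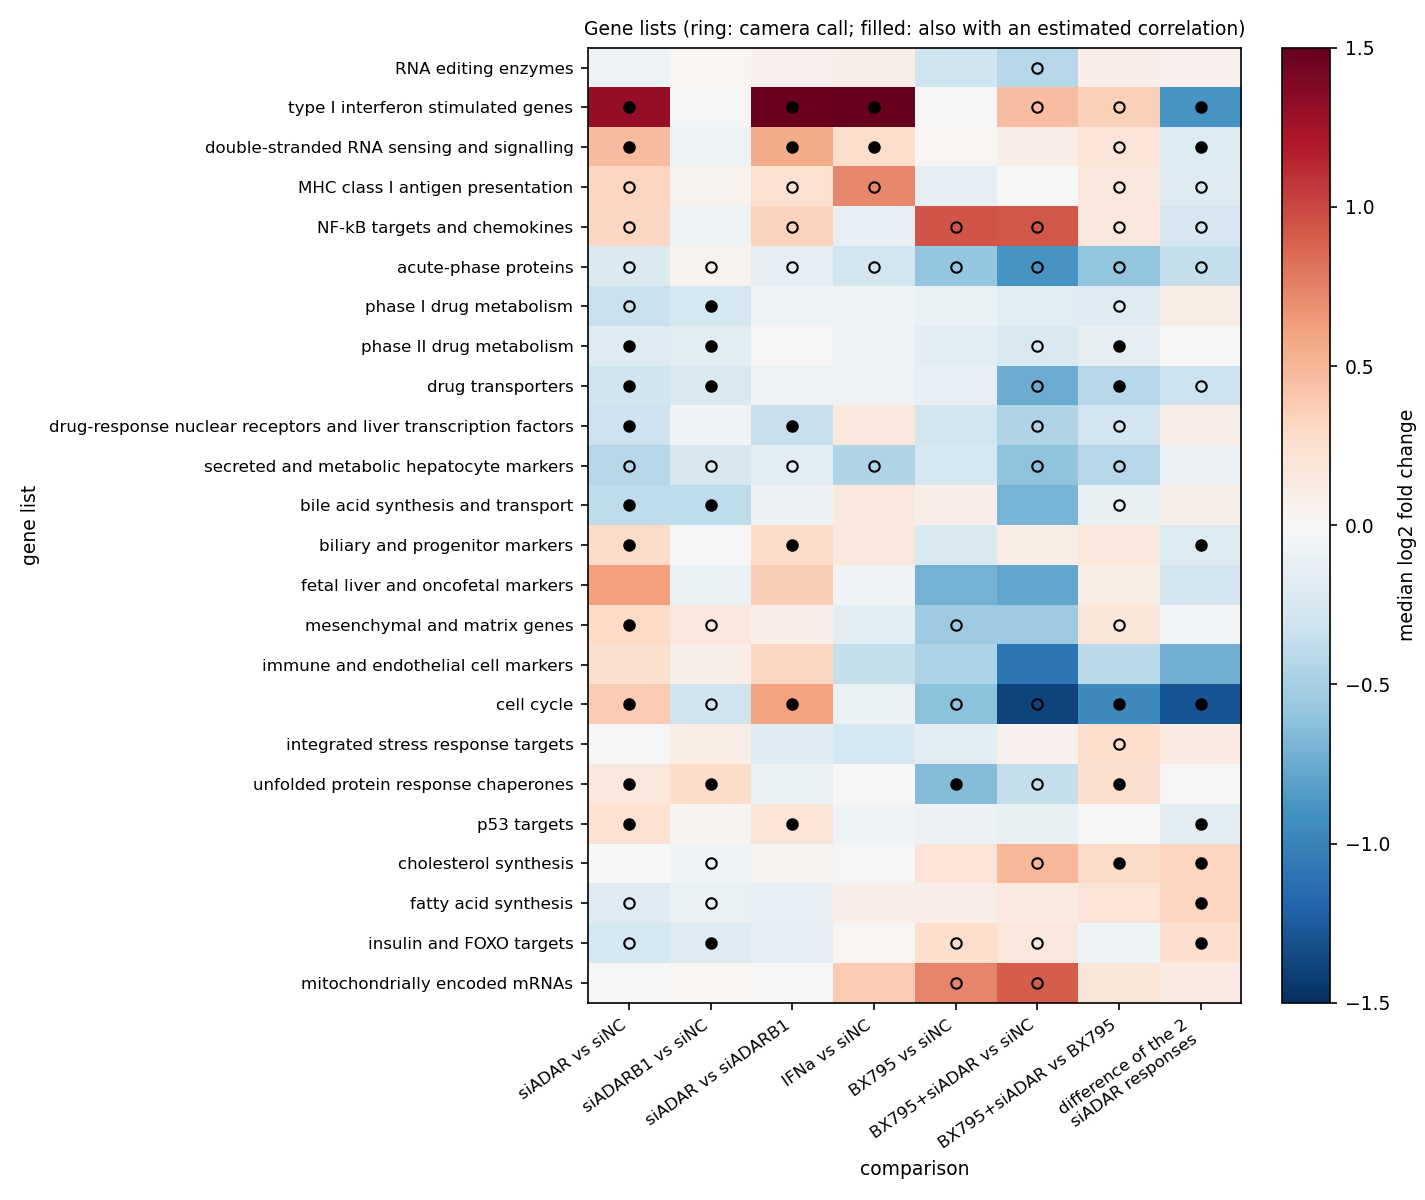
Median log2 fold change (colour) of the gene lists in the 8 comparisons, with a ring where camera called the list and a filled ring where the call held with an estimated correlation. The pharmacogenes as a group are not drawn. Counting them, 19 lists were called after ADAR siRNA and 12 held, and for BX795 with ADAR siRNA against siNC 14 were called and 0 held.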

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

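The test of the difference between the ADAR knockdown responses was planned; the tests of knockdown depth, of the response to IFNa and of the controls of both batches were chosen after the result was seen.

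The response to ADAR siRNA differed between the BX795 groups of batch 2 and the groups of batch 1 in 790 genes. Interferon stimulated genes had a median difference of -0.89 and cell cycle genes one of -1.30. ADAR differed by -0.29, toward the deeper fall with BX795, a difference that was not called. Its RNA thus gave no sign of a shallower knockdown with BX795. However, IFNa raised ADAR itself, so the ADAR level also depends on the interferon response. A shallower knockdown is therefore not excluded by this value. Batch 2 cells were able to respond to interferon, with 52 of 52 list genes raised by IFNa. A batch difference instead of BX795 remains open: the median of the list differed by 0.118 between the controls (15 genes higher and 18 lower in batch 2). With 0 groups of batch 2 given ADAR siRNA without BX795, BX795 and batch cannot be told apart here. Whether the wells with BX795 alone received the control siRNA is also not given, so the difference need not stem from either alone. The cause of the cell cycle difference was not tested.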

How the results depend on the processing

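The splits of libraries between groups, the alternative settings and the pairing check were planned before the data were seen; the GC correction and the tests without control replicates 2 and 3 were chosen after the result was seen.

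Gene counts moved with the choice of model and of libraries, and no named gene called in either setting turned direction. Of the lists, MHC class I with BX795 turned from lower without a call (camera adjusted p = 0.804) to higher after GC correction (adjusted p = 0.0185, adjusted p = 0.299 with an estimated correlation). For ADAR siRNA (5042 genes), a fit of batch 1 alone gave 8156, the compared groups alone 8028 and the 2-fold cutoff 780. For ADARB1 siRNA (1066), DESeq2 gave 1663, batch 1 alone 3557, the compared groups alone 3241 and the replicate block 686. GC correction gave 1838 and the 2-fold cutoff 88. Leaving out 1 library gave 603 (without ADARB1 siRNA replicate 1) to 702 (without batch 1 control replicate 3). For the ADAR against the ADARB1 siRNA (4518), batch 1 alone gave 7676, the compared groups alone 7613 and the 2-fold cutoff 686. For IFNa (7932), batch 2 alone gave 4624, the compared groups alone 1695, the fit without control replicates 2 and 3 (which left 1 control library, here and below) 1966 and the 2-fold test 1119. Leaving out 1 library gave 2652 (without IFNa replicate 1) to 9649 (without batch 2 control replicate 1). For BX795 (10885), the fit without control replicates 2 and 3 gave 4688 and the 2-fold test 2331. For BX795 with ADAR siRNA against siNC (9310), the compared groups alone gave 4188, the fit without control replicates 2 and 3 4671 and the 2-fold test 2088; leaving out 1 library gave 5275 (without replicate 2 of BX795 with ADAR siRNA) to 10499 (without batch 2 control replicate 1). Against BX795 (2201), batch 2 alone gave 712, the compared groups alone 962, the replicate block 1414, GC correction 3353 and the 2-fold cutoff 384. Leaving out 1 library gave 1209 (without replicate 1 of BX795 with ADAR siRNA) to 2100 (without BX795 replicate 1). For the difference of the ADAR responses (790), DESeq2 gave 1211, the replicate block 459, GC correction 1407 and the 2-fold cutoff 271. Leaving out 1 library gave 442 (without replicate 1 of BX795 with ADAR siRNA) to 775 (without replicate 2 of that group). The count was 515 without ADAR siRNA replicate 2. Between the controls (13443) the 2-fold cutoff gave 5381. With an estimated correlation the lists called went from 19 to 12 for ADAR siRNA, 13 to 7 for ADARB1 siRNA, 10 to 6 between them, 5 to 2 for IFNa (9 with fry), 7 to 1 for BX795 (13 with fry), 14 to 0 for BX795 with ADAR siRNA, 17 to 5 for it against BX795, and 12 to 8 for the difference of the ADAR responses. With GC correction as well these counts were 7, 6, 6, 3, 3, 6, 0 and 5 in the same order. The correlation across genes of the ADAR siRNA and IFNa responses (0.063) was 0.159 at 1 CPM or more, 0 without a filter and 0.119 with a stricter one, and 0.023 (without IFNa replicate 2) to 0.081 (without IFNa replicate 1) with 1 library left out. That of the ADAR and ADARB1 siRNA responses (0.427) was 0.273 at 1 CPM or more, 0.474 without a filter, 0.325 with a stricter one and 0.381 with DESeq2, and 0.353 (without ADARB1 siRNA replicate 3) to 0.542 (without batch 1 control replicate 2) with 1 library left out. At 1 CPM or more, simulated unchanged groups sharing the same controls gave a mean r of 0.492 (0.362 to 0.572), above the measured 0.273, and a covariance of 0.021 (0.0149 to 0.027), below the measured 0.034. That of the ADAR siRNA responses with and without BX795 (0.123) was 0.32 at 1 CPM or more, 0.039 without a filter, 0.213 with a stricter one and 0.085 with DESeq2; genes are not independent replicates. In batch 1, libraries with the same replicate number were no more alike (r across genes -0.075 to 0.106) than those with different numbers (-0.092 to 0.131). The paired block was therefore not preferred. In batch 2 the ranges were -0.216 to 0.212 and -0.212 to 0.216. They cannot decide this, since r was taken on deviations from the group mean, which mirror each other in a group of 2 libraries. The cause of these movements was not tested.

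Splitting the 6 libraries of a comparison in all 10 ways gave as many genes in 1 split, the real one, each time: 5042 genes against 0 in the highest other split for ADAR siRNA, 1066 against 1 for ADARB1 siRNA, 4518 against 1 between them and 10885 against 2 for BX795. 10 splits are too few for a share under 0.05, so an accident of grouping is neither excluded nor shown by these splits.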

Other observations

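The tests of depth by thinning, of CYP3A4 without single libraries and of its paralogs were planned before the result was seen; the tests against control replicate 1 alone, of the GC trend of the BX795 libraries, of PXR and CAR target genes and of CYP3A4 with IFNa were chosen after the result was seen.

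A few lists were not called by camera after ADAR siRNA. Among 14 RNA editing enzymes 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.512), the splicing and editing cofactor gene RBM47 by 0.66 ± 0.06. This list holds ADAR itself, and fry called it lower (adjusted p = 1.96e-07). Of 8 fetal liver markers 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0754). PEG10, an imprinted gene active in fetal liver, fell by 1.41 ± 0.08. The fry test called the fetal list higher (adjusted p = 0.0366). Of 8 immune and endothelial markers 1 rose and 1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.66). Of 19 integrated stress response targets 5 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.794, toward higher values; median -0.02), the cytokine gene GDF15 rising by 1.28 ± 0.14.

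Fold changes with BX795 followed the GC content of genes (rho -0.563 across genes, which are not independent replicates). The GC-rich control replicates 2 and 3 may carry part of this pattern: against control replicate 1 alone rho was -0.434, weaker but still present. Sequencing depth remains open: thinning all 10 batch 2 libraries to the lowest depth left the range of GC trends at 1.695, against 1.691 before, but thinning keeps each gene's share of a library and so decides little. Whether BX795 itself adds to it remains open: the highest trend of its libraries (-0.199) lay below that of control replicate 1 (0.283) but above that of IFNa replicate 1 (-0.403). Fold changes with IFNa, without BX795, also followed GC content against control replicate 1 alone (rho -0.296 across genes).

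CYP3A4 rose after ADAR siRNA while most other drug metabolism genes called fell. A wide activation of PXR and CAR targets remains open: 11 other targets had a median log2 fold change of -0.22 ± 0.23 (SE), smaller than its SE. The SE treats these genes as independent. Of the 11 targets, 5 were called lower and 1 higher, CYP3A43 at 1.56 ± 0.31. A single library does not account for the CYP3A4 rise, the lowest fold change without 1 library being 2.19. Reads shared with paralogs do not either: of CYP3A5, CYP3A7 and CYP3A43 only CYP3A5 lost counts, and its loss of 101 CPM was 12.2% of the gain of 834 CPM. Whether interferon alone adds to the rise remains open. CYP3A4 with IFNa stood at 0.73, and at 0.47 after GC correction (edgeR adjusted p = 0.149). IFNa was given in batch 2 only, whose controls stood at a log2 difference of -7.16 in CYP3A4 from those of batch 1. The IFNa value therefore cannot decide what interferon would do to CYP3A4 in the batch 1 cells.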
